A study of Pimephales promelas with 20 samples.

How the data were processed

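RNA abundance in liver was measured on 20 Agilent one-colour oligonucleotide arrays of female fathead minnow (Pimephales promelas), a small North American freshwater fish widely used in aquatic toxicology. Per the labels, the fish were exposed for 48 h and total RNA was extracted with Trizol and labelled with Cy3. Groups and replicate numbers came from the dose label and the sample title. The title number of 287 ng/L replicate 27 follows those at 29 ng/L, but its title prefix and its dose label, which was used, are those of the 287 ng/L arrays. There were 4 groups of 5 arrays at 0, 29, 287 and 1006 ng/L phenanthrene, a polycyclic aromatic hydrocarbon of 3 fused benzene rings found in crude oil and combustion residues. The labels do not say that the arrays came from separate fish, so p-values measure only the spread between these arrays, which may be technical.

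Each array was deposited as scanner output holding intensity values per spot on a linear scale. Per the file headers, these were extracted with Agilent Feature Extraction 10.7.1.1 for a single colour. The processed intensity was already background-subtracted and spatially detrended by that software, per the file headers, and had not been scaled between arrays. Raw median intensity and local background, deposited in the same output, were used for 1 alternative only. Each array held 15744 spots, of which 536 were control spots and 15208 were probes for fish sequences.

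The authors also deposited a table for the whole series, whose sample titles call the values loess normalized. Set against the scanner output, each of its 20 sample columns correlated best with its own array, with r of at least 0.992 to the log2 processed intensity. The authors' deposited values were therefore taken as log2 values with higher meaning brighter, not centred by gene. The medians of the authors' control columns were 5.45, 5.48, 5.50, 5.51 and 5.51. Those at 29 ng/L were 5.45, 5.48, 5.50, 5.58 and 5.60, those at 287 ng/L 5.48, 5.50, 5.53, 5.53 and 5.69, and those at 1006 ng/L 5.39, 5.43, 5.48, 5.50 and 5.51. The authors' loess settings and any further centring of the arrays are not given in the sources used here. No value was given for 714 probes, all in the column of 287 ng/L replicate 36. The table also held 1 column of no sample, which was not used; it equalled the mean log2 processed signal of each probe to within 4.99e-06.

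Values were computed from the scanner output in R 4.3.3 with limma 3.58.1. Control spots were left out, and 240 spots that the scanner software marked as outliers, all of them as non-uniform, were set to missing. Of these, 201 lay on 29 ng/L replicate 22. The 8 saturated spots, all on that same array, were kept. The log2 processed signal was normalized between arrays by cyclic loess, each array against the mean array, because the titles name loess. Probes were tested where they were well above background on at least 4 arrays of at least 1 group, which left 10867 probes, or 71.5% of all. Brightness over background limits what dim probes can show, and the number of arrays limits the precision.

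All 20 arrays entered 1 linear model with a coefficient per group, fitted with lmFit and eBayes, so that the groups shared an estimate of the spread. Comparisons were each dose against the controls, each dose against each other dose, an F test of the 3 dose coefficients, and a trend over the dose rank from 0 to 3. All tests were two-sided, except the F test, and p-values were adjusted by the Benjamini-Hochberg method over the probes tested in each comparison. A probe passed at an adjusted p under 0.05. An ordinary linear model without moderated variances was run as a second tool. Correlations of fold changes between doses share their controls. They were therefore set beside values from 100 draws in which arrays were regrouped at random after removal of the group means, and beside 10 splits that gave 3 controls to one dose and 2 to the other. The same simulations were run for the direction of called probes at the other doses, and repeated with unchanged groups and 1 split of the controls per draw, a step added after the values had been seen.

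These comparisons, their settings and the rule for naming genes were fixed before the data were examined. The rule named the genes with the largest rises and falls among those past the threshold, the leading genes of gene lists, and a fixed set of liver genes. It could not be applied. The arrays name probes by an array identifier and a contig, clone or sequence number, and 0 of these names were found in the table of genes used here. For the same reason none of the 34 planned gene lists was tested. In their place, the probes with the largest 2 rises and the largest 2 falls among those past the threshold at 1006 ng/L are given by their identifiers, with no gene name. For probes near background this order by size holds for the processed signal only.

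The tests were run on simulated data with known changes. The simulated noise was normal and drawn independently for each probe and array, so variation shared between probes and outlying arrays were left out. The shares below hold for that setting and may differ on the real arrays. Among 10867 simulated probes, 200 were changed in each of 10 draws by a log2 change of 1 or 2 at the top dose, with smaller changes at the lower doses. For 1006 ng/L against control, 9.5% of the changes of 1 and 56% of the changes of 2 were recovered, and 5.07% of calls were false. For the trend the shares were 13.7% and 61.8%, with 3.33% of calls false, and for the F test 3.6% and 42.6%, with 6.85% false. For 287 ng/L against control they were 0.9% and 18.8%, with 6.19% false. For 29 ng/L against control, where the simulated changes were the smallest, none was recovered. Between doses, where simulated differences were smaller than those of the top dose from control, the shares were 0.5% and 17.6% for 1006 against 29 ng/L, 0% and 0% for 1006 against 287 ng/L and 0% and 0.1% for 287 against 29 ng/L. Of the calls made there, 3.72%, 100% and 50% were false in the same order.

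Slide and scan session were read from the scanner output. Slides 3 and 4 held 8 arrays each, 2 per group, and formed scan session 1. The other 4 arrays, 1 per group, lay on slides 1, 2 and 5 in scan session 2. Alternatives covered scaling between arrays, background correction, the authors' values, the filter on dim probes, spots marked by the scanner software, slide, array weights, the prior variance, the arrays in the fit, the threshold, the dose scale and leaving out each array in turn. A normexp correction (offset 50) planned on mean signals was run on median signals, since the scanner output held no mean signals. That correction was chosen after seeing the data. So were scan session (as a block, session 1 alone, and the trend in session 2 alone), array brightness and the first principal component as model terms, the removal of arrays with variable spike-in signals, the treatment of position on the array and the trend without controls. Position on the array was examined in 96 blocks, 12 by 8, of spot positions. Figures were drawn with matplotlib 3.10.9.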

Results

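Liver gene expression of female fathead minnows was measured after 48 h of exposure to phenanthrene, a polycyclic aromatic hydrocarbon, with 5 arrays at each of 0, 29, 287 and 1006 ng/L. The series was designed to follow gene expression over dose. On each array between 8722 and 12797 of the 15208 fish probes were well above background, or 57.4% to 84.1%. The mean number per group was 10132 ± 1349 (SD, n = 5) in controls, 10318 ± 1367 at 29 ng/L, 11391 ± 1408 at 287 ng/L and 10689 ± 1186 at 1006 ng/L. The 75th percentile of processed signal lay between 151 and 684 intensity units, with a median of 324. No probe could be paired with a gene name, so probes are described by number, size and direction, and 4 of them by array identifier.

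Arrays of the same dose were about as similar to each other as arrays of different doses. The median correlation across tested probes was 0.902 for array pairs within a group and 0.900 for pairs from different groups, and single pairs ranged from 0.774 to 0.948. Probes are not independent replicates, so these values describe similarity only. The first principal component held 29.7% of the variance and the second 10.6%. Mean scores on the first component were -27.8 ± 40.6 (SD, n = 5) in controls, -2.89 ± 63.1 at 29 ng/L, -3.89 ± 43.5 at 287 ng/L and 34.6 ± 64.3 at 1006 ng/L, so the groups overlapped. Of the second component's squared scores, 86.2% belonged to 29 ng/L replicate 22 alone, and the next array held 4.10%.

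**Figure D1:**
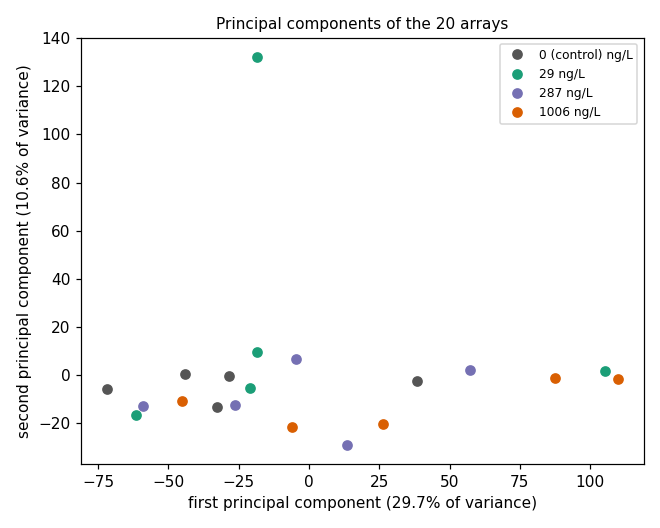
Scores of the 20 arrays on the first principal component (x axis, 29.7% of variance) and the second (y axis, 10.6%) of normalized log2 signal, coloured by dose. The doses overlap along the first component, and 29 ng/L replicate 22 lies apart on the second at 132.

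A pair of arrays had a dim region near the centre. On 287 ng/L replicate 36 the mean deviation from the median array was under -0.50 log2 units in 10 of 96 blocks of spot positions, which held 1065 tested probes. On 1006 ng/L replicate 42 it was so in 8 blocks with 849 tested probes. The lowest block means were -2.80 and -1.95, and 0 blocks on the other 18 arrays were that dim. Of the 22 probes that passed at 1006 ng/L, 1 lay in a dim block of 287 ng/L replicate 36 and 0 in those of 1006 ng/L replicate 42.

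**Figure D2:**
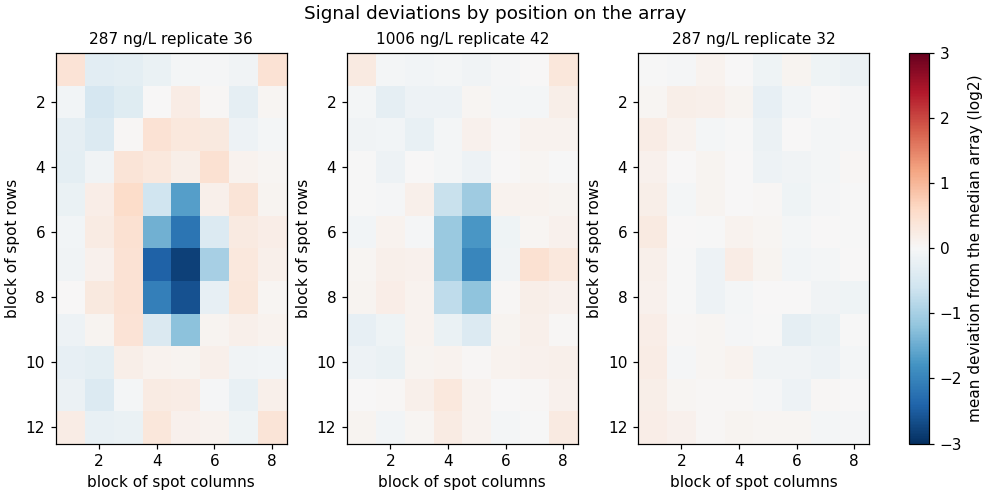
Mean deviation of tested probes from the median array (log2, colour scale) in 96 blocks of spot positions on 287 ng/L replicate 36, 1006 ng/L replicate 42 and, for comparison, 287 ng/L replicate 32. The dim central blocks reach -2.80 on the first array and -1.95 on the second.

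At the highest dose, 1006 ng/L, 22 of 10867 probes differed from the controls, of which 20 rose and 2 fell. Their log2 changes had a median size of 1.87 and ran from 1.13 to 4.11. The largest rise was that of probe UF_Ppr_AF_112748, whose mean log2 signal was 7.17 ± 0.54 (SD, n = 5) in controls and 11.28 ± 0.47 at 1006 ng/L, a 17.2-fold difference. Probe UF_Ppr_AF_112570 rose from 2.97 ± 1.20 to 5.96 ± 0.40, with 2 of the 5 controls well above background. The probes that fell were UF_Ppr_AF_106468, from 7.60 ± 0.32 to 4.25 ± 1.37 with 3 of the 5 exposed arrays well above background, and UF_Ppr_AF_101957, from 9.42 ± 0.20 to 7.79 ± 0.32.

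With limma's moderated test the log2 change of UF_Ppr_AF_112748 was 4.11 (SE 0.47), at an adjusted p of 0.000392. For UF_Ppr_AF_112570 it was 2.99 (SE 0.55, adjusted p = 0.0230), for UF_Ppr_AF_106468 -3.36 (SE 0.60, adjusted p = 0.0177) and for UF_Ppr_AF_101957 -1.63 (SE 0.29, adjusted p = 0.0177). In all 22 probes the 5 exposed arrays lay entirely beyond the 5 controls, which was also true of 3.77% of all tested probes and is given by chance in 0.794%. The 22 were picked on these same arrays, so their separation is no added support. At an unadjusted p under 0.05 there were 1416 probes, 692 higher and 724 lower, where chance alone gives 543 on average. Probes vary together between arrays, so a count given by chance can lie far from that average. The ordinary linear model called 31 probes, the 22 among them. UF_Ppr_AF_112570 in controls and UF_Ppr_AF_106468 at 1006 ng/L lay near background, so their sizes and their rank by size are not exact: with normexp background correction they were 0.77 (adjusted p = 0.0845) and -1.28 (adjusted p = 0.0402).

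Within slide 3, with 2 arrays per group, the log2 changes of these 4 probes at 1006 ng/L were 3.96 for UF_Ppr_AF_112748, 2.44 for UF_Ppr_AF_112570, -3.46 for UF_Ppr_AF_106468 and -1.67 for UF_Ppr_AF_101957. Within slide 4 they were 4.20, 3.26, -3.87 and -1.71 in the same order. On slide 3 alone limma called 0 probes at this dose, with 1494 at an unadjusted p under 0.05, 0 by the ordinary linear model and a lowest adjusted p among these 4 of 0.281. On slide 4 alone the counts were 0, 600 and 0, and that p was 0.760. Each slide held as many control as 1006 ng/L arrays, so slide as a block cannot move these changes. The median size of the 22 was thus 1.87 with the block too. The median SE went from 0.319 to 0.333 and the residual degrees of freedom from 16 to 12. With slide as a fixed block limma called only UF_Ppr_AF_112748 of all tested probes (adjusted p = 0.00565), where the ordinary linear model called 6. The median adjusted p of the 22 was then 0.0555. As a random block, slide left the same 22 probes called, with a fitted correlation within slides of -0.0164. Scan session 1 alone, with 4 arrays per group, gave 1 probe, and session as a block 25.

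The number called at 1006 ng/L moved by over 1.5 times without single arrays. It was 1 without control replicate 7, 3 without control replicate 3 or 1006 ng/L replicate 41, 5 without control replicate 4, 6 without 1006 ng/L replicate 44 and 11 without replicate 46 of that dose. It was 34 without control replicate 6, 50 without 29 ng/L replicate 22 and 69 without 29 ng/L replicate 26. UF_Ppr_AF_112748 passed in all 20 of these fits, UF_Ppr_AF_112570 in 13, and UF_Ppr_AF_106468 and UF_Ppr_AF_101957 in 15 each.

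**Figure D3:**
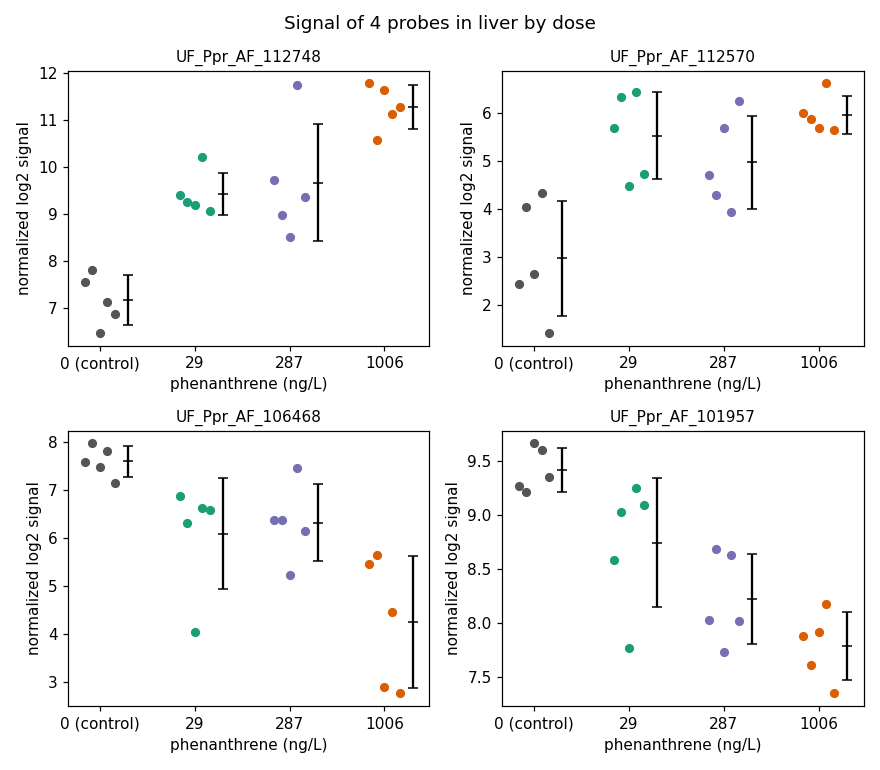
Normalized log2 signal (y axis) of the 4 probes with the largest 2 rises and largest 2 falls at 1006 ng/L, by phenanthrene dose in ng/L (x axis). Points are arrays and bars are group means with SD (n = 5); UF_Ppr_AF_112748 runs from 7.17 in controls through 9.43 and 9.67 to 11.28.

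At 29 and at 287 ng/L no probe passed. With limma 0 probes were called at 29 ng/L against control, with 612 at an unadjusted p under 0.05 and 0 by the ordinary linear model. At 287 ng/L the counts were 0, 592 and 0, and chance alone gives on average 543 probes under 0.05. The lowest adjusted p was 0.302 at 29 ng/L and 0.379 at 287 ng/L. Probe UF_Ppr_AF_112748 was at both of these values. Its mean log2 signal was 9.43 ± 0.45 (SD, n = 5) at 29 ng/L and 9.67 ± 1.25 at 287 ng/L, log2 differences of 2.26 and 2.50 from the controls (SE 0.47 each). Without 287 ng/L replicate 27, this probe passed at 29 ng/L (adjusted p = 0.0239), as the 1 probe called there. That array had the highest value of the probe at 287 ng/L, 11.75, above the next there (9.74) and all at 29 ng/L (9.07 to 10.21). Its replicate number adjoins those of the 29 ng/L arrays, 22 to 26, and lies apart from the other numbers at 287 ng/L, 32 to 38. Its dose label, used here, gives 287 ng/L, and its title has the same prefix, Med, as the other arrays at 287 ng/L.

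The 22 probes called at 1006 ng/L were shifted the same way from the controls at the lower doses, 21 of them at 29 ng/L and 22 at 287 ng/L. In the direction of the change at 1006 ng/L their median log2 difference was 0.94 at 29 ng/L and 1.07 at 287 ng/L. All doses were set against the same 5 controls, and probes picked at one dose then tend to shift the same way at another. In simulations with unchanged groups, as many probes picked at another group had median differences of 0.84 (95% of draws between 0.15 and 1.58) and 0.84 (0.21 to 1.38), with 20.4 and 20.5 probes in the same direction on average. The observed values lay within these ranges. For probes picked with 3 of the controls and set against the other 2, the mean over 10 splits was 0.68 at 29 ng/L (0.16 to 1.09) and 0.84 at 287 ng/L (0.50 to 1.14), with 17.1 and 19 of 22 probes in the same direction on average. Unchanged groups, with 1 split of the controls per draw, gave means of -0.02 (95% of draws between -1.09 and 0.94) and -0.09 (-1.38 to 1.01), and 10.8 and 10.3 probes. The observed mean sizes were reached in 10% and 5% of these draws, and the observed numbers of probes in 16% and 8%. A single split can vary more than a mean over 10 splits, so these draws cannot decide the question. A shift of these probes at the lower doses was thus neither shown nor excluded.

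Over the 4 doses 31 probes showed a trend, 26 upward and 5 downward. UF_Ppr_AF_112748 rose by 1.26 log2 units per dose step (adjusted p = 0.00128). UF_Ppr_AF_101957 fell by 0.54 per step (adjusted p = 0.00981) and UF_Ppr_AF_106468 fell by 0.98 (adjusted p = 0.0354). UF_Ppr_AF_112570 did not pass, at 0.84 per step (adjusted p = 0.0863). The trend of UF_Ppr_AF_106468 passed in 8 of the 20 fits without 1 array and in 16 of 45 settings in all, with adjusted p from 0.00503 to 0.818, while those of UF_Ppr_AF_112748 and UF_Ppr_AF_101957 passed in all 20 fits and in 40 of 46 settings. Of the 31 probes, 18 had also passed at 1006 ng/L, a comparison made on the same arrays. At an unadjusted p under 0.05 there were 1482 probes, 698 upward and 784 downward, against 543 by chance on average. The balance toward rises among the 31 was thus not seen in this wider set. The ordinary linear model called 37.

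Among the 3 phenanthrene doses without the controls the trend gave 0 probes with limma, 869 at an unadjusted p under 0.05 and 0 by the ordinary linear model. With slide as a block it gave 8. It gave 0 on slide 3, on slide 4 and in scan session 1 alone, with 1373, 596 and 1939 at an unadjusted p under 0.05 and 0 by the ordinary linear model in each. In scan session 2 alone, with 1 array per dose, it gave 0, 775 and 0. By single arrays it was 4, 5 and 6 without control replicates 4, 3 and 7, and 8, 10, 12, 13 and 16 without 1006 ng/L replicates 44, 46, 41, 42 and 45. Without 29 ng/L replicate 25 or 287 ng/L replicate 35 it was 15, without 29 ng/L replicate 23 it was 19, without 29 ng/L replicate 22 it was 60 and without 29 ng/L replicate 26 it was 106.

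**Figure D4:**
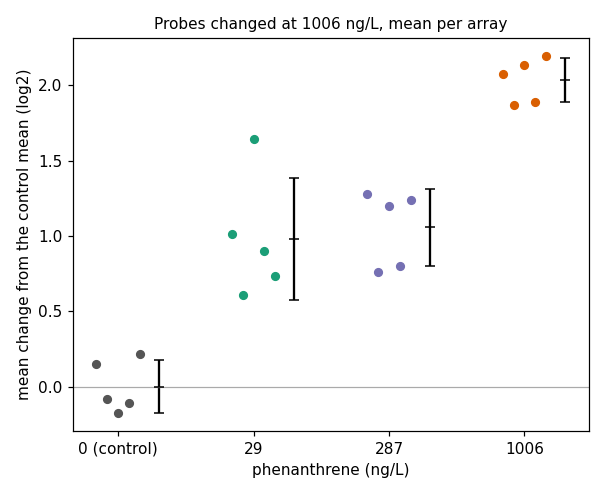
Mean log2 difference from the controls of the 22 probes called at 1006 ng/L, turned so that the change at that dose is upward (y axis), by phenanthrene dose in ng/L (x axis), with a point for each array. Group means are 0 in controls, 0.98 at 29 ng/L, 1.06 at 287 ng/L and 2.03 at 1006 ng/L; the probes were picked on the control and 1006 ng/L arrays shown.

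The F test asked whether any dose differed and called 4 probes, all of them among the 22 and UF_Ppr_AF_112748 one of them. There were 846 probes at an unadjusted p under 0.05, and the ordinary linear model called 5. With slide as a block limma called 0 in the F test, with 855 at an unadjusted p under 0.05. It called 0 on slide 3, on slide 4 and in scan session 1 alone, with 1127, 326 and 1085, and the ordinary linear model called 0 in all of these. The number was 28 without 29 ng/L replicate 26, and 2 without control replicate 5, 287 ng/L replicate 32, 287 ng/L replicate 36 or 1006 ng/L replicate 45. It was 1 without any single one of the other 15 arrays.

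No probe passed between one dose and another. For 1006 against 29 ng/L limma called 0 probes, with 968 at an unadjusted p under 0.05, 0 by the ordinary linear model and a lowest adjusted p of 0.0574. For 1006 against 287 ng/L the counts were 0, 517 and 0, with a lowest adjusted p of 0.209. For 287 against 29 ng/L they were 0, 461 and 0, with 0.994. UF_Ppr_AF_112748 was higher by 1.85 log2 units at 1006 than at 29 ng/L (adjusted p = 0.320) and by 1.61 than at 287 ng/L (adjusted p = 0.885), neither past the threshold. The 22 probes were thus called against the controls at 1006 ng/L and not at the lower doses, while 0 of them passed between 1006 ng/L and either lower dose. All 22, which were picked at 1006 ng/L, lay further from the controls there than at either lower dose. On simulated data the tests between doses recovered few changes, 17.6% of those of 2 log2 units at the top dose for 1006 against 29 ng/L and 0% for 1006 against 287 ng/L, so the counts of 0 do not show that the doses were alike. Their mean oriented difference from the controls was 0.98 ± 0.40 (SD, n = 5) at 29 ng/L and 1.06 ± 0.25 at 287 ng/L, a difference of 0.08 with a two-sided exact permutation p of 0.722 over 252 splits, where the smallest possible is 0.00794.

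The count for 1006 against 29 ng/L was 18 without 29 ng/L replicate 26, 5 without 287 ng/L replicate 36 and 1 without 287 ng/L replicate 32, 1006 ng/L replicate 42 or 1006 ng/L replicate 45. For 1006 against 287 ng/L it was 1 without 287 ng/L replicate 32 or 1006 ng/L replicate 45. For 287 against 29 ng/L it was 2 without 29 ng/L replicate 26 and 2 within slide 3 alone.

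Log2 differences from the controls correlated between doses across the 10867 tested probes, at r = 0.567 for 29 and 287 ng/L, 0.549 for 29 and 1006 ng/L and 0.634 for 287 and 1006 ng/L. The doses share their controls, and unchanged groups gave mean correlations of 0.507 (95% of draws between 0.124 and 0.803), 0.501 (0.119 to 0.743) and 0.505 (0.0941 to 0.766). The covariances were 0.191, 0.255 and 0.291 beside simulated means of 0.199, 0.191 and 0.199, which left differences of -0.00734, 0.0646 and 0.0922. With the controls split, r averaged 0.0768, 0.167 and 0.227, with ranges over the 10 splits of -0.0609 to 0.230, -0.0907 to 0.354 and -0.0445 to 0.415. The observed correlations lay within the simulated ranges. Without 29 ng/L replicate 26 the correlation of 29 and 1006 ng/L was 0.233, and within slide 3 alone it was 0.352, that of 29 and 287 ng/L 0.493 and that of 287 and 1006 ng/L 0.422. Within slide 4 alone the correlations were 0.741 for 29 and 287 ng/L, 0.711 for 29 and 1006 ng/L and 0.650 for 287 and 1006 ng/L.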

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

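Tests on array brightness, the first component and slide for the 1006 ng/L count, on marked spots for 29 ng/L replicate 22 and on array regions for the spike-in signals were chosen only after the results were seen.

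In 44 sets of 5 arrays, 10 held an array far from the others by Dixon's ratio (over 0.71), where chance gives about 1 in 20, or 5%. The 75th percentile of signal was 684 on 1006 ng/L replicate 45, against 246 to 368 on the other arrays of its dose. The spike-in signals, from RNA added in known amounts, had a CV of 8.20% on 29 ng/L replicate 22 (others 2.69% to 4.003%), 30.1% on 287 ng/L replicate 36 (3.72% to 6.40%) and 14.4% on 1006 ng/L replicate 42 (3.25% to 4.95%). Spots marked non-uniform numbered 7 on control replicate 4 (0 to 2), 201 on 29 ng/L replicate 22 (0 to 5) and 5 on 1006 ng/L replicate 45 (0 to 1). Control replicate 3 had a mean correlation of 0.867 with all other arrays (0.896 to 0.902). On the first component 29 ng/L replicate 26 scored 105 (-61.6 to -18.5), and its log2 signal of UF_Ppr_AF_106468 was 4.05 (6.32 to 6.88).

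For each comparison 100 splits of the arrays, the real one included, were counted. At 1006 ng/L, 1 of the 100 splits, the real one, gave as many as 22 probes, and the highest other split gave 1. That share is the lowest these splits can give. It argues against chance only for arrays split without regard to slide. The real split correlated at r = 0.544 with the first component of the arrays and the highest other split at 0.587. For the F test 2 of 100 splits gave at least the real 4 probes, with 4 as the highest other. That share, too, argues against chance only for arrays split without regard to slide, and another split equalled the real count. With slide as a fixed block the F test called 0 probes by limma and 0 by the ordinary linear model, with 855 at an unadjusted p under 0.05. At 1006 ng/L limma then called 1 and the ordinary linear model 6, while slide as a random block left 22 by limma. For the trend 2 of 100 did, with 31 in the real split and 461 in the highest other. That split correlated at r = -0.634 with the first component, against 0.391 for the real one, and so many calls point to a structure of the samples. Correlation with the first component alone did not give many calls, since a split for 287 against 29 ng/L at r = 0.667 gave 2. For 29 ng/L and for 287 ng/L against control, with 0 real probes by limma and a highest other of 1 each, all 100 splits reach that count by construction, so the splits decide nothing about chance. They decide nothing between doses either, with 0 real probes in each and a highest other of 1099 for 1006 against 29 ng/L, 1 for 1006 against 287 ng/L and 2 for 287 against 29 ng/L. The split with 1099 correlated at r = -0.813 with the first component and likewise points to a structure of the samples. At an unadjusted p under 0.05 these 5 comparisons had 612, 592, 968, 517 and 461 probes, and 0 adjusted calls each by the ordinary linear model.

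More probes passed at 1006 ng/L (22) than at the lower doses (0 each by limma), although 0 passed between doses. Against array brightness as the whole cause, the median change of the 22 kept 0.933 of its size (SE 0.0730) with brightness in the model. Against slide differences, each slide held as many control as 1006 ng/L arrays, so an additive difference between slides cancels from this comparison. In addition, 22 probes ranked anew on the other slides had median changes of 1.26 within slide 3 and 1.56 within slide 4. Both lay at or above the percentile 99.97 of random lists. Picked probes can vary together more than random ones, so this percentile does not measure chance between arrays. Of the re-ranked probes 22 and 20 kept their direction, beside 64.3% and 69.5% of all tested probes. Only 7 and 12 of them were among the 22 called with all arrays. With the first component in the model the median went from 1.87 (SE 0.319) to 1.59 (SE 0.318) and the calls from 22 to 10, a ratio of 0.852 (SE 0.131) that does not clear 0.8 by its error, so a part of that component in the change cannot be told apart. An effect of phenanthrene at 1006 ng/L stays open as a hypothesis, beside unlabelled differences between the fish.

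One array, 29 ng/L replicate 22, stood apart on the second component, with a score of 132 against -28.8 to 9.49 elsewhere. A fault in a region of the array was argued against, since 1.57% of its deviations lay between blocks of spot positions, within the 0.970% to 36.4% (median 1.96%) of the other arrays. Its marked spots were argued against as the cause, since it held 86.2% of the squared scores with those spots already missing. The RNA, the fish and the labelling reaction stay open. No biological explanation was tested, because the design gives none for a single array.

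The spike-in signals of 287 ng/L replicate 36 and 1006 ng/L replicate 42 varied the most. A fault in a region of the array is a candidate explanation: 36.4% and 21.7% of their deviations lay between blocks of spot positions, against at most 3.07% on the other 18 arrays. Over 161 spike-in spots, deviations followed those of the fish probes in the same block at r = 0.830 and 0.656, against -0.0988 to 0.249 elsewhere. With the dim blocks missing, 23 probes passed at 1006 ng/L. No biological explanation was tested, because spike-in RNA does not come from the fish.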

How the results depend on the processing

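Scan session, normexp, brightness and first-component terms, arrays removed together, position on the array and the trend without controls were chosen only after the data were seen; the other alternatives were planned.

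Gene lists, camera, fry and the mean of a gene's probes were not run, since no probe could be named; normexp on mean signals became median signals. Scan session 2, with 1 array per group, allows a test of the trend but none between groups. No paired analysis was possible because the replicate numbers do not overlap between groups. No change of the 4 probes given by identifier reversed, and signal over background limits dim probes. Each of the 22 probes passed at 1006 ng/L in 27 to 45 of 47 alternatives. These include other thresholds on the same fit, which none of the 22 could fail, and 20 fits without 1 array. The tally is thus no measure of independent support. Over 43 settings the change of UF_Ppr_AF_112748 at 1006 ng/L was 3.51 to 4.31 and passed in 41. That of UF_Ppr_AF_112570 was 0.77 to 3.48 (past in 28 of 42), of UF_Ppr_AF_106468 -3.87 to -1.28 (31 of 42) and of UF_Ppr_AF_101957 -1.73 to -1.24 (32 of 43). Each was smallest with normexp, whose offset shrinks dim probes by construction. Counts are given for 1006 ng/L (22), the trend (31), the F test (4) and, where named, comparisons at 0. The cause was not tested unless stated.

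Scaling to the 75th percentile gave 14, 17 and 1, and moved the median of all probes at 1006 ng/L to -0.21, from -0.03 with loess; the 22 probes then had a median size of 1.72. Quantile normalization gave 38 and 54, and 1 for 1006 against 29 ng/L. Median scaling gave 15 for the trend, 1 for the F test and 1 for 1006 against 29 ng/L. The authors' values gave 27, with all 22 among them, 39 for the trend, 1 for the F test and 1 for 1006 against 29 ng/L. No filter gave 10 for the trend and 1 for the F test. Probes well above background on all 20 arrays gave 44 and 68. Outlier spots kept gave 2 for the F test. A fixed slide block gave 1, 8 and 0, with fewer residual degrees of freedom. A random block gave 22, 29 and 2. Slides 3 and 4 alone, with 8 arrays each, gave 0, 0 and 0, slide 3 also 2 for 287 against 29 ng/L and r = 0.422 between 287 and 1006 ng/L (0.634) and 0.352 between 29 and 1006 ng/L (0.549), which on slide 4 was 0.711. Array weights gave 88, 176 and 44, with 1 at 29 ng/L, 22 for 1006 against 29 ng/L and 1 for 1006 against 287 ng/L. Trend and robust eBayes gave 34 at 1006 ng/L, and the 2 groups alone, with 10 arrays fewer, 7. A looser threshold of 0.10 gave 61, 92 and, for 1006 against 29 ng/L, 4; a fold of at least 1.5 per step left 11 for the trend. Unadjusted p under 0.01 gave 407, 472 and 218, with 115 at 29 ng/L and 122 at 287 ng/L. Between doses it gave 244 for 1006 against 29 ng/L, 92 for 1006 against 287 ng/L and 70 for 287 against 29 ng/L. Chance gives 109 on average in each. Dose on a linear scale gave 5 for the trend, and the 3 doses alone 0.

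Session as a block gave 1 for the F test, session 1 alone 1, 0 and 0, and session 2 alone, with 4 arrays, 0 for the trend. Normexp gave 1 for the F test, and so did centred position blocks. Brightness in the model gave 15 for the trend, 2 for the F test and 4 for 1006 against 29 ng/L. The first component in the model gave 10 and 9. Without the 2 arrays of most variable spike-ins the trend gave 15, 1006 against 29 ng/L 4 and 1006 against 287 ng/L 1. Without these and 29 ng/L replicate 22 there were 46 at 1006 ng/L, 2 for 1006 against 29 ng/L and 1 for 1006 against 287 ng/L.

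Leaving out each array in turn gave 1 to 69 at 1006 ng/L, 4 to 106 for the trend, 1 to 28 for the F test, 0 to 1 at 29 ng/L, 0 to 0 at 287 ng/L, 0 to 18 for 1006 against 29 ng/L, 0 to 1 for 1006 against 287 ng/L and 0 to 2 for 287 against 29 ng/L. The correlations ran from 0.400 to 0.698 for 29 and 287 ng/L, 0.233 to 0.688 for 29 and 1006 ng/L and 0.499 to 0.7497 for 287 and 1006 ng/L. Arrays that move a count are named beside it in the text on each comparison; the highest were without 29 ng/L replicate 26 at 1006 ng/L and for the trend, the F test, 1006 against 29 ng/L and 287 against 29 ng/L, without 287 ng/L replicate 27 at 29 ng/L, and without 287 ng/L replicate 32 or 1006 ng/L replicate 45 for 1006 against 287 ng/L.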

Other observations

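The tests of the first component, and of the called probes' correlation with that component fitted out, were chosen only after the results were seen.

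The first component had Pearson's r of 0.517 with log2 brightness over the 20 arrays (permutation p = 0.0203, adjusted 0.0608 over 3 relations). Spearman's rho was 0.308 (permutation p = 0.187). Without the 2 arrays of most extreme brightness, both on slide 3, r was 0.346 (permutation p = 0.157). Within slides 3 and 4 r was 0.613 and 0.553, and rho 0.595 and 0.238. With dose, rho was 0.411 (permutation p = 0.0759, adjusted 0.114), and r with the log10 of dose was 0.371 (permutation p = 0.110). Without 1006 ng/L replicates 45 and 46, an arbitrary choice among the arrays of the top dose, that r was 0.368. Within slides 3 and 4 rho with dose was 0.732 and 0.586. The means of slides 3 and 4 differed by -35.3, or 0.596 of the SD of their 16 arrays (exact permutation p = 0.244). None of the 3 relations passed after adjustment, and none was shown to be absent.

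A hypothesis was that the probes called at 1006 ng/L vary together from array to array within a dose. The mean within-group correlation of 21 called probes with complete values, turned by direction, was 0.258. Among 10000 random lists of as many tested probes the median was 0.0631 and the 95th percentile 0.162, which put the called probes at the percentile 99.81. With the scores of the first component fitted out, the mean was 0.235, above all random lists. Those scores still held the differences between groups, so the component was removed within groups only in part. The called probes were picked on these same arrays, and probes picked together can vary together even in unchanged groups. Random lists do not allow for this, so a source of variation beyond dose was neither shown nor excluded. Fish and handling were not separable here either. Since the called probes varied together, the calls are not 22 independent results. For scale, 200 pairs of probes for the same sequence had a median within-group correlation of 0.261, and random pairs -0.0112.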
